A study of Mus musculus and Homo sapiens with 4 samples.

How the data were processed

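The material was 2 lists of Miz1 ChIP-seq peaks, 1 from mouse neuronal progenitor cells (antibody H190) and 1 from the human line labelled MDA-MD-231 (antibody G18). Per the labels' protocols, chromatin was crosslinked with 1% formaldehyde for 10 minutes at 37 °C and sonicated to fragments averaging under 500 bp. DNA of about 200 bp was then cut from a gel, amplified with 18 PCR cycles and sequenced on an Illumina Genome Analyzer IIx, per the labels. CASAVA, FastQC, Bowtie 0.12.7 and MACS 1.4.2 are named in the submitters' processing notes, as are the builds mm9, hg19 and GRCh37. The settings of these tools, the use of the input as a control in peak calling, and read totals are not given in the sources used here. Each peak list belongs to a single library.

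Each deposited list gives a chromosome, a start, an end, a peak name and a score per peak, with no header. The score is a deposited value of the authors, taken here as that of their peak caller from the peak names and the place of the column. Neither the lists nor the labels define it or its scale, and nothing says that it is scaled between libraries. It was used to describe each list and to rank or filter peaks within it, and the scores of the lists were not tested against each other. Scores have a ceiling at 3100, where 35 mouse and 159 human peaks tie, so these peaks cannot be ranked against each other or against the few listed above 3100. No list held overlapping peaks or peaks on unplaced contigs. Coordinates are printed counting from 1, in mm9 for the mouse list and hg19 for the human list, the builds named for each species in the submitters' processing notes.

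The gene table used holds GRCm38.p6 mouse genes, another build than mm9. Taken as they stand, 23 of the 261 mouse peak centres lay within 1000 bp of an end of a protein-coding gene in that table, against a median of 11 and a maximum of 23 for 200 random shifts of the list. Because the builds differ, the table was used only to count protein-coding genes per chromosome (21631 on the autosomes and X) and to measure each autosome from its first to its last gene. No coordinates were converted, so peaks were not assigned to genes, promoters, motifs or sequence, and the tests fixed in advance for these were not run: promoter share, genes with a peak, the 11 gene lists, genes shared between the lists, and the Miz1 motif. The test of human peak number against gene number per chromosome was not run either.

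The spacing, score-width and mouse gene-number tests, most of their alternatives and the rule for named sites were fixed before the data were examined. Where genes could not be named, the rule was the 10 peaks of highest score in each list and the chromosomes with the most and the fewest peaks per gene. Because 3100 is a capped value with many ties, 10 peaks could not be chosen, and the 4 mouse and 2 human peaks listed above it are given without a rank among all peaks. The merging of close peaks in these tests, the removal of blocks, of the 2 widest mouse peaks and of genes named Olfr or Vmn, the wide peaks at the ceiling, the blocks, the tests of single chromosomes and of scores between chromosomes were chosen after the values were seen.

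Correlations were Pearson's r and Spearman's rho with two-sided permutation p-values from 100000 permutations. Spacing was the share of peaks whose centre had another centre within 10 kb, set against 1000 random placements of the centres on the same chromosomes up to each chromosome's last peak. Random placement does not allow for mappability or gene density. Single chromosomes were tested with exact two-sided binomial tests, against their share of protein-coding genes in mouse and of the span between first and last peak in human. A block was a run of at least 4 peaks with gaps under 1 kb. Adjusted p-values are Benjamini-Hochberg within each family. The threshold was 0.05.

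The tests were tested on simulated lists with the peak number of each real list (autosomal peaks only for the partial correlation and for higher against lower scores), with 50 lists per setting. The spacing test called 100% of lists with planted close pairs and 0% without, in both lists. The planted lists held a larger share of peaks with a near neighbour than the real lists, so power at the observed shares was not measured. The binomial tests called a chromosome raised to 2.5 times its weight in 72% of simulated mouse lists and in 100% of human ones. They called some other chromosome in 4% of mouse and 8% of human lists with nothing planted, and in 2% and 14% with 1 planted. The gene-number correlation was called in 100% of mouse lists drawn by gene number and in 4% of lists drawn with equal chance per chromosome. Lists drawn by chromosome length were not simulated for this correlation, so how often length alone would give a call was not measured. A chromosome with scores raised by 1.5 SD was found in 40% of mouse and 100% of human lists, and unplanted lists were called in 8% of both. The score-width correlation was called in 100% of planted and 4% of unplanted lists of both kinds. The test of the fullest window of 1 Mb was called in 100% of planted lists of both kinds, and in 0% of mouse and 2% of human lists without. The planted windows held more peaks than the fullest real windows (6 in mouse and 18 in human), so power at the observed sizes was not measured. The comparison of a set with random sets was called in 100% of planted lists of both kinds, and in 4% of mouse and 8% of human lists without. The test of scores of neighbouring peaks was called in 66% of planted mouse and 100% of planted human lists, and in 2% and 10% without. The difference between higher and lower scores was called in 74% of planted and 2% of unplanted mouse lists, and the partial correlation in 86% and 4%. The partial correlation was simulated given the span of the peaks only, not given the length from the first to the last gene.

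Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were a higher score minimum (the list's median), leaving out the widest 5% of peaks, merging peaks less than 1 kb apart, a spacing of 100 kb, and adding chromosome X.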

Results

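Binding of Miz1 to chromatin was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in 2 kinds of cell. Miz1 is a zinc-finger transcription factor that binds DNA directly and also partners the oncoprotein MYC. The first kind was mouse neuronal progenitor cells, taken from the brain at stage E13.5 and expanded as neurospheres, with the antibody H190. The second was the line labelled MDA-MD-231, of human origin, with the antibody G18. Each kind of cell had 1 Miz1 library and 1 input library of unselected chromatin DNA, and a peak list was used for each Miz1 library. Values of the input libraries were not analysed here, so no background level stands beside the peaks. The read depth of the libraries is not given in the sources used here, and with 1 Miz1 library per kind of cell no value has a replicate error. Species, antibody and kind of cell differ together between the 2 lists, so no test was made between them. Intervals treat the peaks of 1 list as units and cover counting error only. Tests also treat peaks as units, apart from correlations across chromosomes, whose units are chromosomes. Neither intervals nor tests measure variation between libraries.

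The first comparison sets out where and how strongly Miz1 was called bound in each kind of cell, in a study of the part Miz1 plays in autophagy. In mouse progenitor cells 261 peaks were called on 20 chromosomes, covering 70.4 kb in all. In MDA-MD-231 cells 2911 peaks were called on 24 chromosomes, covering 1251 kb. The mouse peaks were narrow, with a median width of 239 bp (quartiles 193 and 313 bp), and 4 of them were wider than 500 bp. The human peaks had a median width of 346 bp (quartiles 252 and 489 bp), and 698 of them, or 24.0% (95% Wilson interval 22.5 to 25.6%), were wider than 500 bp.

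Each list was also described by its own scores, which are not known to be scaled between the libraries. The authors' score of a peak had a median of 494 in progenitor cells (quartiles 179 and 2166) and of 185 in MDA-MD-231 cells (quartiles 127 and 396). Scores piled up at a ceiling of 3100, which 39 mouse peaks reached or passed, or 14.9% of the list (95% Wilson interval 11.1 to 19.8%). In the human list 161 peaks did so, or 5.53% (95% Wilson interval 4.76 to 6.42%). Peaks scoring below 200 numbered 73 of 261 in the mouse list and 1583 of 2911 in the human list. No peak in either list scored below 100. Scores may depend on read depth, which is not known for either library. These shares therefore describe the lists and not the occupancy of the factor, and no direction between the lists is read from them.

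In progenitor cells 4 peaks were listed above 3100. They lay on mouse chromosome 2 (mm9, bases 32091974 to 32092328, score 3189.5), chromosome 6 (bases 92164760 to 92165015, score 3166.8), chromosome 4 (bases 44085393 to 44085802, score 3106.9) and chromosome 11 (bases 88017608 to 88017991, score 3100.1). A further 35 mouse peaks shared the score of exactly 3100, a capped value, so no strongest site can be named. Among these 35, the widest outside chromosome 17 were on chromosome 11 (bases 23565789 to 23566459, 671 bp) and on chromosome 1 (bases 164500440 to 164500905, 466 bp). In MDA-MD-231 cells 2 peaks were listed above 3100, on human chromosome 19 (hg19, bases 1935371 to 1936330, score 3224.6) and on chromosome 7 (bases 116593281 to 116594646, score 3159.1). Another 159 human peaks tied at the capped value of 3100, so here too no strongest site can be named. The widest of them were on chromosome 10 (bases 104179224 to 104182184, 2961 bp), chromosome 11 (bases 65381151 to 65383811, 2661 bp) and chromosome 14 (bases 66973953 to 66976325, 2373 bp). The gene, exon or promoter at these sites is not given, because no annotation of mm9 or hg19 was used here.

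Higher-scoring peaks were wider in both lists. In progenitor cells the median width was 310 bp for the 131 peaks at or above the median score and 193 bp for the other 130. Across mouse peaks the score rose with the width (Spearman's rho = 0.83, two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). Pearson's r was 0.41 (p = 1e-05), and 0.72 (p = 1e-05) with the 2 widest peaks, both on chromosome 17, left out. It was 0.77 with the widest 5% of peaks left out, and 0.24 among the peaks at or above the median score. In MDA-MD-231 cells the medians were 400 and 291 bp, and the relation across 2911 peaks was rho = 0.45 and r = 0.60 (both p = 1e-05). Without the widest 5% of human peaks r fell to 0.42. The median width of the peaks at the ceiling was 353 bp in the mouse list and 1068 bp in the human list. Adjusted over the 6 coefficients computed, these p-values were 1.5e-05. Width and score, as taken here, both come from the same peak calling on the same library. A relation between them may follow from the calling itself and is no evidence on the sites of Miz1. Peaks are not independent replicates, and the difference between the lists was not tested.

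The distribution of Miz1 peaks over mouse chromosomes was then compared with the number of genes each carries. Chromosomes with more protein-coding genes carried more peaks: across the 19 autosomes Spearman's rho was 0.73 (two-sided permutation p = 0.00074, adjusted p = 0.00089) and Pearson's r was 0.60 (p = 0.0067, adjusted p = 0.0067). Without chromosomes 7 and 2, which lie farthest from the median gene number, r was 0.62 (permutation p = 0.0078). Peak number also rose with the span between the first and last peak of a chromosome (rho = 0.61, permutation p = 0.0066), which itself widens as peaks are added. With the length from the first to the last gene, a measure free of the peaks, rho was 0.48 (permutation p = 0.036). Pearson's r with that length was 0.40 (permutation p = 0.089). For the peaks at or above the median score rho with gene number was 0.85, and for the others it was 0.17. Chromosome 17 had the most peaks per gene, with 24 peaks or 22.7 per 1000 genes, followed by chromosome 18 with 11 peaks or 21.5 per 1000 genes and chromosome 5 with 27 peaks or 21.3 per 1000 genes. The fewest were on chromosome X, with 4 peaks or 4.14 per 1000 genes, and on chromosome 15, with 4 peaks or 5.15 per 1000 genes. Among peaks at or above the median score chromosome 14 had the fewest, with 0 peaks. Chromosome 18 came next with 1, below X at 2.07 per 1000 genes. The order at the top turned when peaks less than 1 kb apart were counted once: chromosome 18 then had the most, with 21.5 per 1000 genes, chromosome 5 had 20.5, and chromosome 17, with 18 peaks left, came below both. It turned another way for the higher-scoring peaks alone. Chromosomes 5 and 17 then led, with 9.46 and 9.44 per 1000 genes, and chromosome 18 fell to 1.96.

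No single mouse chromosome passed an exact two-sided binomial test against its share of genes after adjustment over 20 chromosomes, while 3 had an unadjusted p under 0.05. Chromosomes 17 and 5 held 1.88 and 1.76 times their expected number (both adjusted exact p = 0.051). Chromosome X held 0.34 times its expected number (adjusted exact p = 0.11). With peaks less than 1 kb apart counted once, chromosome 17 fell to 18 peaks, or 1.45 times the expected number (adjusted exact p = 0.36). With genes named Olfr or Vmn left out of the expected shares and all 24 peaks counted, including the 6 of a single block, it was called above, at 1.93 times (adjusted exact p = 0.042).

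**Figure D1:**
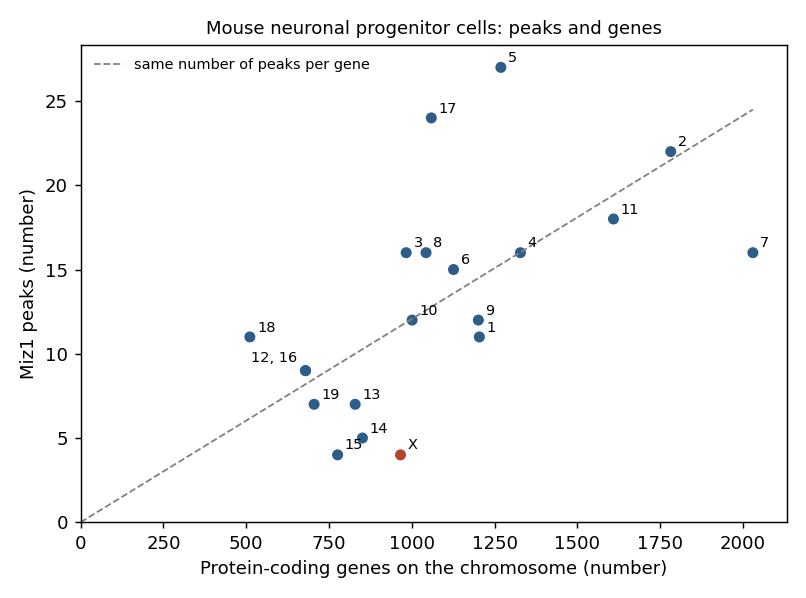
Each point is a mouse chromosome, placed by its number of protein-coding genes (horizontal axis) and its number of Miz1 peaks in neuronal progenitor cells (vertical axis), with X in red and a dashed line at an equal number of peaks per gene. Chromosomes 17 (24 peaks) and 5 (27 peaks) lie above the line and X (4 peaks) lies below it.

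Scores also differed between mouse chromosomes. Chromosome membership accounted for 13.4% of the variance of score ranks, where 7.31% is expected with no difference (permutation p = 0.010, adjusted over both lists p = 0.021). The 16 peaks of chromosome 4 had a median score of 2520, and 6 of them reached the ceiling. The 16 peaks of chromosome 7 had 7 at the ceiling, with a median of 718. The 11 peaks of chromosome 18 had a median of 150 and none at the ceiling. In the human list chromosomes accounted for 1.10% of the variance of ranks, where 0.757% is expected with no difference, and this did not pass the test (permutation p = 0.078, adjusted p = 0.078).

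In MDA-MD-231 cells peak density differed widely between chromosomes. Chromosome 19 carried 2.95 peaks per Mb of the span between its first and last peak, and chromosome 17 carried 2.60. Chromosome 13 carried 0.37 and chromosome X 0.39. As background, human chromosomes 19, 17 and 22 are known to be rich in genes and chromosomes 13 and 18 to be poor in them; gene number was not tested in this list. In exact two-sided binomial tests against the share of the total span, adjusted over 23 chromosomes, 7 chromosomes lay above and 7 below their expected number of peaks. Those above were chromosome 19 (173 peaks, 2.94 times the expected number, adjusted exact p = 4.06e-33), chromosome 17 (211 peaks, 2.59 times, adjusted exact p = 4.06e-33), and chromosomes 22 (1.94 times), 20 (1.93 times), 11 (1.43 times), 1 (1.31 times) and 14 (1.24 times). Those below were chromosome 13 (33 peaks, 0.37 times, adjusted exact p = 2.81e-11), chromosome X (60 peaks, 0.39 times, adjusted exact p = 1.05e-17), and chromosomes 18 (0.56 times), 4 (0.57 times), 3 (0.68 times), 7 (0.73 times) and 2 (0.75 times).

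The call for chromosome 22 depended on how the span was measured: counted from base 1 of the chromosome it held 1.28 times its expected number (adjusted exact p = 0.075). The call for chromosome 14 was also lost, at 1.04 times (adjusted exact p = 0.68), and chromosome 21 was called below, at 0.59 times (adjusted exact p = 0.0052) against 0.70 times by the span between first and last peak (adjusted exact p = 0.10). Counting from base 1 adds the stretch before the first peak, which holds no peak of the list. It lengthened chromosome 22 from 32.3 to 51.2 Mb, chromosome 14 from 84.7 to 105.5 Mb and chromosome 21 from 38.2 to 47.9 Mb. Whether peaks could be called in that stretch was not examined, so the low value of chromosome 21 cannot be read as a depletion. Among peaks at or above the median score chromosome 14 turned to 0.92 times its expected number (adjusted exact p = 0.70) and chromosome 2 was at 0.87 times (adjusted exact p = 0.22), while chromosome 8 was called below (0.72 times) and chromosome 16 above (1.36 times). Copy number in this line was not analysed here, and 2 peaks on chromosome Y were left out of these tests.

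**Figure D2:**
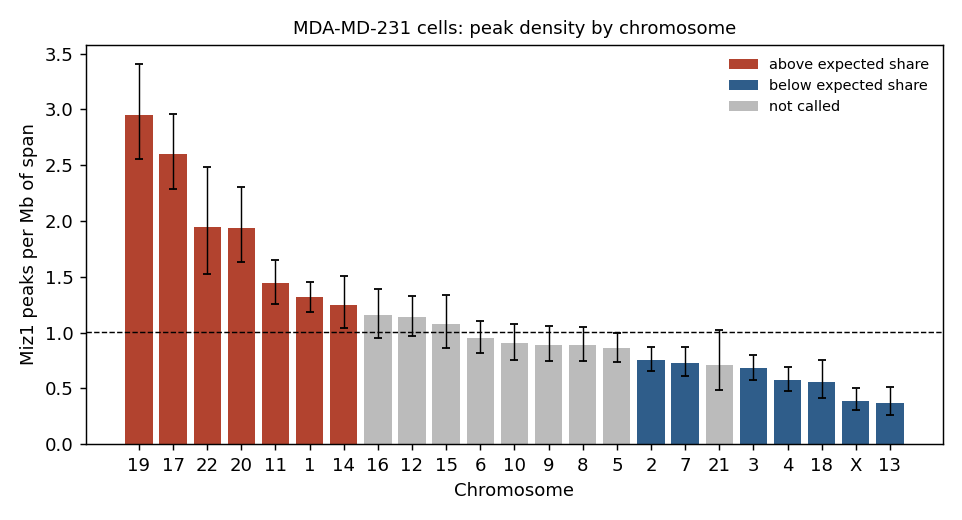
Bars give Miz1 peaks per Mb of span for each chromosome in MDA-MD-231 cells, ordered from highest to lowest, with error bars for the 95% Wilson interval of the chromosome's share of all peaks and a dashed line at the mean density. Red and blue bars are the 7 chromosomes above and the 7 below their expected number, led by chromosome 19 with 2.95 peaks per Mb and ended by chromosome 13 with 0.37.

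Peaks in both kinds of cell lay closer together than random positions. In progenitor cells 22 of 261 peaks, or 8.43%, had another peak within 10 kb, while random placement on the same chromosomes gave 0.25% on average and 2.30% at most over 1000 draws (one-sided permutation p of positions = 0.001, the smallest these draws can give). In MDA-MD-231 cells 466 of 2911 peaks, or 16.01%, had such a neighbour, against 2.41% on average and 3.68% at most in random placements (permutation p = 0.001). With peaks less than 1 kb apart merged into one, the shares were 3.95% of 253 mouse peaks and 9.67% of 2791 human peaks (both permutation p = 0.001).

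The densest region in progenitor cells was a block of 6 peaks on chromosome 17 (mm9, bases 39979921 to 39985784). It held the widest peaks of the list, of 3421 bp and 1358 bp, both at the score ceiling, with 4 peaks of 91 to 360 bp between them. Gaps inside the block were 50 to 98 bp, and 5544 of its 5864 bp were covered by peaks. The window of 1 Mb around it was the only mouse window with 6 peaks, where random placements gave 5 at most (permutation p = 0.001). Those 6 peaks are the peaks of the block, so the window test counts again how 1 nearly continuous stretch was divided into peaks. It is no separate evidence of a dense region. This block supplied 6 of the 22 mouse peaks with a near neighbour, and without it the share was 6.27% (permutation p = 0.001).

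In MDA-MD-231 cells the block with the most peaks lay on chromosome 1 (hg19, bases 16268424 to 16275040). Within 6.62 kb it held 8 peaks, 5 of them at the score ceiling and the lowest at 1994. The peaks were 221 to 1167 bp wide, with gaps of 116 to 873 bp. The gene under this block, and whether it is the gene that encodes Miz1 itself, was not determined here. Another 3 blocks of 4 peaks were found, on chromosome 2 (bases 1346113 to 1350074, median score 631) and on chromosome 17 (bases 18964631 to 18967980, median score 227, and bases 19090733 to 19094124, median score 306). None of the peaks in these 3 blocks reached the ceiling. The human window of 1 Mb with the most peaks was on chromosome 4 between 49 and 50 Mb, with 18 peaks, where random placements gave 13 at most (permutation p = 0.001). Of these, 17 lay within 50.9 kb (bases 49281734 to 49332660), with a median score of 154 and none at the ceiling. The 18 peaks were wide but low in score: their median width was 882.5 bp, against 346 bp in the list, and their median score was 160, against 185. Windows on chromosome 11 (118 to 119 Mb) and chromosome 19 (44 to 45 Mb) held 13 peaks each (both permutation p = 0.003). Another 3 windows with 12 peaks each (permutation p = 0.006) bring the windows that passed to 6: they lay on chromosome 1 (16 to 17 Mb, around the block above, and 156 to 157 Mb) and on chromosome 6 (3 to 4 Mb). Of the 12 peaks between 16 and 17 Mb, 8 are the peaks of the block. That window therefore mostly counts the block again and is no separate evidence of a dense region. The windows were not counted again with close peaks merged.

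**Figure D3:**
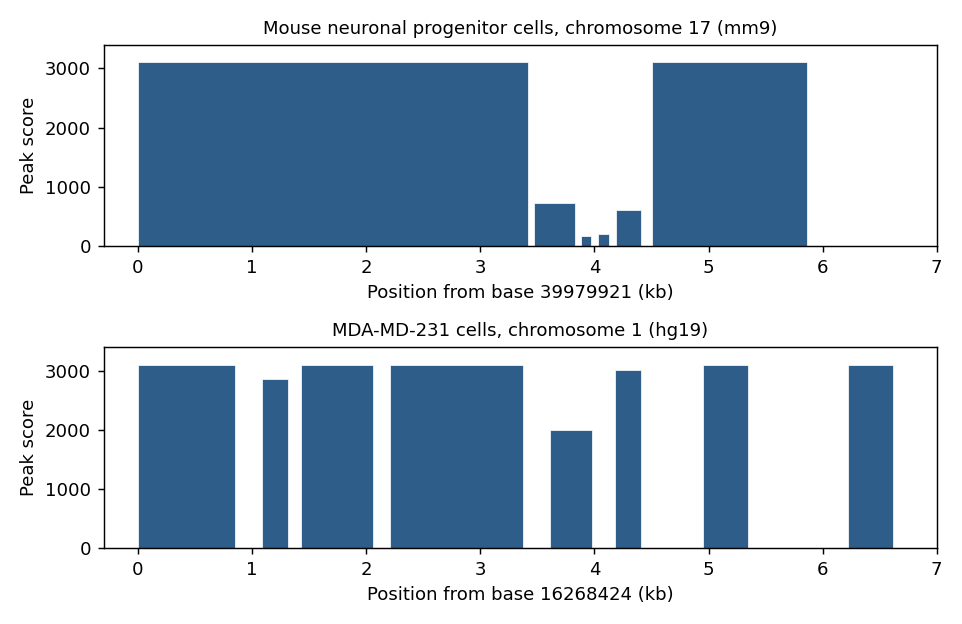
Bars are the peaks of the mouse block on chromosome 17 (upper panel) and of the human block on chromosome 1 (lower panel), drawn to scale along the chromosome in kb from the first base of the block, with the authors' score as height. The mouse block has 2 wide peaks at 3100 with 4 weaker ones between them, and the human block has 8 separate peaks scoring from 1994 to 3100.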

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

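The merging of peaks in the spacing and chromosome tests, the removal of blocks, of the 2 widest mouse peaks and of receptor genes, and the other measure of span were chosen after the data were seen. Of 34 alternatives over 13 results, 31 kept the direction and the side of the threshold, or a count within 1.5 times. By construction, keeping peaks at or above the median score left 131 mouse and 1456 human peaks. The number of mouse chromosomes off their expected share went from 0 to 1 when genes named Olfr or Vmn were left out: chromosome 17 then held 1.93 times its expected number (adjusted p = 0.042, exact binomial test), with fewer genes counted. The share of peaks with a near neighbour, 3.95 to 15.7% in mouse and 9.67 to 44.8% in human, lay above the highest random placement in each alternative run. At 100 kb the excess was smaller relative to chance: 15.7% against a random mean of 2.42% (at most 6.90%) in mouse, and 44.8% against 21.0% (at most 24.3%) in human. Spearman's rho of peaks with genes per mouse chromosome ranged from 0.67 without the widest 5% of peaks to 0.85 for the higher-scoring peaks. For score and width it ranged from 0.60 to 0.83 in the mouse and from 0.38 to 0.45 in the human list. The number of human chromosomes called was 13 or 14, and 12 of the 14 remained for the higher-scoring peaks (lost: 2 and 14, the latter turning from 1.24 to 0.92 times; gained: 8 and 16) and 12 with spans from base 1 (lost: 14 and 22; gained: 21). Alternatives for promoters, gene lists, shared genes, motifs and human gene number were not run, since no gene or sequence was assigned. No paired analysis was possible because each kind of cell has a single Miz1 library. Read depth is unknown, so how many sites the mouse library could have shown at a greater depth is open.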

Other observations

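The comparisons of peak blocks and of the window on chromosome 4 with random sets were chosen after these had been seen, as was the reading of the spacing excess against the highest random draw; the spacing test itself was planned. The test of higher-scoring against lower-scoring mouse peaks was also added after the higher-scoring peaks had been seen to follow gene number more closely. The test given the length between first and last gene was added after the test given the span of the peaks had been seen. The tests given the span of the peaks, on receptor genes, on scores of neighbouring peaks and on human density were specified before their results were seen.

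Strong and weak Miz1 peaks of mouse progenitor cells were spread differently over the autosomes. The 129 autosomal peaks at or above the list's median score followed the number of protein-coding genes per chromosome with Spearman's rho = 0.85, and the other 128 with rho = 0.17. The difference of 0.67 had a one-sided permutation p of 0.0002 when the scores were reassigned among the peaks, which measures the pattern on the data that showed it and is no independent evidence. It was 0.71 (permutation p = 0.0002) with peaks less than 1 kb apart merged, 0.70 (p = 0.0004) without chromosome 17 and 0.72 (p = 0.0008) without chromosome 5. Chromosome length is argued against as the whole reason for the relation with genes over all peaks, since the partial rank correlation was 0.62 (permutation p = 0.00455) given the length from the first to the last gene of each chromosome in the gene table, a measure free of the peaks though from another build. Given the span of the peaks themselves it was 0.52 (permutation p = 0.020). Leaving out 1465 genes named Olfr or Vmn changed rho by -0.0013, which decides nothing, since families that add genes but few peaks would weaken the relation and not produce it. A hypothesis is that many peaks near the caller's minimum may lie apart from genes, which would need positions of genes in mm9 to test; a biological difference between strong and weak sites stays open.

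The human block on chromosome 1 (bases 16268424 to 16275040) is the pattern most worth following up. Clutter of weak peaks near the caller's minimum is argued against: the median score of its 8 peaks was 3100 and the lowest 1994, where the upper quartile of the list was 396. The block was singled out by its number of peaks and its scores, so its place above the 95th percentile of random sets of 8 peaks (437) is no separate evidence. The other 3 human blocks had median scores at the 58th, 74th and 92nd percentiles of random sets of 4 peaks. The peaks covered 4266 of 6617 bp and stood apart by gaps of up to 873 bp. A DNA copy of a spliced transcript in the library, such as an expression construct, may give separate strong peaks over exons, but this cannot be told apart from several true binding sites without exon positions in hg19. Whether the block lies over the gene that encodes Miz1 itself was not determined here, and its scores would then have another reading. No input values were used, and the input library would be the first place to look.

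The mouse block on chromosome 17 differs from it, since its peaks nearly touch. Their mean width was 924 bp, a value set by the 2 wide peaks that drew attention to the block, so it is no separate evidence. Their median score was 664, at the 57th percentile of random sets of 6 peaks. A sequence present in several copies and folded onto 1 place of the reference could give such broad coverage. A peak list holds no copy number, and no annotation or sequence of mm9 was used. Such copies could therefore not be told apart here from broad binding of Miz1.

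The share of peaks with a neighbour within 10 kb, 8.43% in the mouse and 16.01% in the human list, lay above the highest of 1000 random placements (2.30% and 3.68%). In MDA-MD-231 cells peaks with a near neighbour scored 27.7 higher in the median than the rest (209 against 181, permutation p = 0.0015, adjusted p = 0.0030). In progenitor cells they scored -31.8 relative to the rest (466 against 498, permutation p = 0.87, adjusted p = 0.87). Both tests treat peaks as independent, although peaks with a near neighbour come in pairs and runs that may share signal. The human test also called 10% of simulated lists with nothing planted, so its p-value may be too small. The 18 peaks of the human window on chromosome 4 had a median score of 160.4, against 186 in the median of random sets and 301 at their 95th percentile. Clutter of weak peaks near the caller's minimum would give a median at or below the list's 185, as was seen. In width the 18 peaks were unlike weak peaks of the list: their median was 882.5 bp, against 291 bp for human peaks below the median score. The width was not tested against random sets, and the explanation stays open for this window on its scores only. The human densities of higher-scoring and lower-scoring peaks per chromosome followed each other (Spearman's rho = 0.87, permutation p = 1e-05, 23 chromosomes). With neighbouring peaks merged, 100% of the 14 chromosomes called were called in the same direction. Merging took the tested peaks only from 2909 to 2789, so this check could change few calls and says little about neighbouring peaks. The 2 human blocks on chromosome 17 had spans of 3350 and 3392 bp with 4 peaks each.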
